A study of Homo sapiens with 6 samples.

How the data were processed

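The samples were 6 RNA-seq libraries of SZ95 sebocytes, 3 transfected with a mock plasmid and 3 with a TRPV3-overexpression plasmid, 24 h per the labels. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit for Illumina. The submitters' processing notes name the aligner HISAT2 2.0.5 and the genome build hg38. The counting tool and its strand setting are not given in the sources used here, so reads of a gene and of a gene that overlaps it on the opposite strand cannot be told apart with certainty. Groups and replicate numbers were taken from the labels, and each column of the table was matched to its sample by group and replicate number.

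The deposited table holds FPKM per gene and library, per the file headers, together with a gene length and coordinates for 58735 genes. All 58735 genes have the coordinates and merged exon lengths of GENCODE 29, which was compared as a reference. FPKM times gene length gave whole multiples of 1 step in each library for 100% of values (tolerance 0.02 reads), so whole reads were recovered as an added step. They totalled 17.5, 16.0 and 17.4 M reads in mock replicates 1 to 3 and 18.4, 17.9 and 17.4 M reads in TRPV3 replicates 1 to 3. The divisor behind the deposited FPKM differed from these totals by between -3.93% and 4.78% and, up to a constant, equalled a median-of-ratios size factor computed from the recovered reads in all 6 libraries (tolerance 0.001%). At these depths 3 reads, the count that 0 reads still allow, correspond to between 0.165 and 0.185 FPKM for a gene of 1 kb; this covers counting error only. The chi-square per degree of freedom between replicates of a group was between 2.52 and 54.2, so no library was a repeat of another within sampling noise.

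Values were analysed as log2(FPKM + 1), with R 4.3.3 and limma 3.58.1. The 12177 genes with a mean of at least 1 FPKM over all 6 libraries were tested with a linear model of group, limma's empirical Bayes with a mean-variance trend, and Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. All adjusted p-values come from limma or from its camera test. Each of 23 gene lists, with 481 genes, was fixed before the data were examined, and 19 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists. The same test with an estimated correlation is given beside it, and the number of members called when adjusted over the list alone beside the number called over all genes. TRPV3 itself stood in no list. An exact two-sided permutation test was run for TRPV3.

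The genes to name were set by a rule before the data were examined. It took TRPV3; up to 10 called protein-coding genes with the largest rise and 10 with the largest fall whose groups did not overlap; from each list that was called, or had at least 3 called members, its called members (up to 4) and, where fewer than 2 were called, its 2 members of highest mean FPKM; called members of the chemokine, cytokine and fatty acid lists (up to 6); and in any case CXCL8, IL6, IL1B, TNF and PTGS2. It named 32 genes, of which 1 is not reported here. Other genes named are said to have been chosen after their values were seen.

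The test was tried on simulated data for the comparison of 3 with 3 libraries, with 65 or 64 tested genes changed 1.5-fold, 66 changed 2-fold and 62 changed 4-fold. The simulated reads had a single dispersion, 0.00216, taken from the mock libraries alone. This leaves out the spread of TRPV3 replicate 1 beyond gene length, so the shares recovered do not hold for the real libraries. Among 12184 genes with no length trend the test made 4 false calls among 180. It recovered 78.5% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 98.4% of those changed 4-fold. With the length trends of the real libraries, among 12180 genes, it recovered 76.6%, 95.5% and 100%, with 7 false calls among 181; voom with sample quality weights made 21 false calls among 207. Of 20 simulated lists shifted by 0.3 on the log2 scale 20 were called, and of 20 unshifted lists 1 was. Simulated genes were drawn independently, so these counts do not cover lists of genes that vary together.

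Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-of-ratios, TPM and quantile scaling, limma without trend, the replicate number as a block, each library left out, an estimated correlation for lists, and a 2-fold minimum. Alternatives chosen after seeing the data were removal of a gene-length trend (lowess, span 0.3), scaling to total recovered reads, limma-voom on the recovered reads with all libraries, with sample quality weights, without TRPV3 replicate 1 or without that library and mock replicate 3, protein-coding genes only, and limma on log2(FPKM + 1) without both those libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No sequence reads were realigned.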

Results

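The series profiled RNA of SZ95 cells, an immortalised human cell line derived from the sebaceous gland. The cells were transfected with a mock plasmid (3 libraries) or with a plasmid that overexpresses TRPV3 (3 libraries), 24 h per the labels. TRPV3 is a calcium-permeable, warmth-activated cation channel best known from keratinocytes. The design text names the role of TRPV3 in inflammation of sebocytes as the question, and states that the replicates are biological. The limma p-values of single genes therefore reflect the spread between those samples. Camera compares the members of a list with the other genes. At the preset correlation its p-values reflect mainly the spread between genes, not that between libraries. The values are the deposited FPKM (fragments per kilobase of gene, scaled for depth). Whole reads could be recovered from them, and the totals were 17.5, 16.0 and 17.4 M reads for mock replicates 1 to 3 and 18.4, 17.9 and 17.4 M reads for TRPV3 replicates 1 to 3. Fold changes below are fitted log2 fold changes of FPKM + 1, TRPV3 plasmid against mock, which understate the change of low genes, and values are mean FPKM ± SD with n = 3 per group.

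The transfected gene was read out first, since it checks the labels. TRPV3 (ENSG00000167723, chromosome 17, 3510502 to 3557995, minus strand, hg38) was at 0.404 ± 0.0400 FPKM with the mock plasmid and 648 ± 103 FPKM with the TRPV3 plasmid, a 1606-fold ratio of means. The 3 mock libraries held 75, 57 and 74 TRPV3 reads, and the 3 TRPV3 libraries held 92523, 117359 and 126249, or 0.504%, 0.656% and 0.725% of their reads. The log2 fold change was 8.84 (SE 0.12, limma adjusted p = 2.7e-07). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries can give. FPKM divides by the 9780 bases of all annotated TRPV3 exons, whereas the longest coding sequence is 2373 bases, and which part the plasmid carries is not given in the sources used here. TRPV3 shares 441 exonic bases with SPATA22 on the same strand, and SPATA22 had no read in any TRPV3 library.

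Few other genes passed the adjusted limma test with all libraries, and all that passed were higher with TRPV3. Of 12177 genes tested, 5 rose and 0 fell: TRPV3 itself, the heat-inducible chaperone gene HSPA6, the neutrophil chemokine CXCL8, the plasminogen activator inhibitor SERPINB2 and the inflammatory cytokine IL6. HSPA6 rose from 0.707 ± 0.0969 to 11.4 ± 1.13 FPKM, CXCL8 from 0.841 ± 0.122 to 4.57 ± 0.791 FPKM, IL6 from 2.65 ± 0.153 to 6.28 ± 0.710 FPKM and SERPINB2 from 3.93 ± 0.30 to 8.26 ± 0.228 FPKM. In each of these genes every TRPV3 library lay above every mock library. Among 19 gene lists tested, those of chemokines, inflammatory cytokines, the NF-kB pathway, interferon-stimulated genes and immediate-early genes were shifted upward with a preset and with an estimated correlation between genes. Genes of fatty acid and sebum lipid synthesis were not shifted as a list.

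The 4 genes beside TRPV3 are known stress or inflammation genes. HSPA6 (ENSG00000173110, chromosome 1, 161524540 to 161526910, plus strand) had a log2 fold change of 2.86 (SE 0.10, limma adjusted p = 7.11e-05). Its near-identical pseudogene HSPA7 went from 2, 2 and 0 reads in the mock libraries to 20, 13 and 16 in the TRPV3 libraries, and reads cannot be divided between such copies with certainty. CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716, plus strand) had a log2 fold change of 1.59 (SE 0.12, limma adjusted p = 0.0146). SERPINB2 (ENSG00000197632, chromosome 18, 63871692 to 63903890, plus strand) had 0.91 (SE 0.08, limma adjusted p = 0.0214). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand) had 0.99 (SE 0.09, limma adjusted p = 0.0370). SERPINB2 shares 547 exonic bases with SERPINB10 on the same strand, which had at most 14 reads in a library. IL6 shares 428 exonic bases with AC073072.1 and 46 with STEAP1B on the opposite strand, and these had at most 11 and 15 reads in a library.

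**Figure D1:**
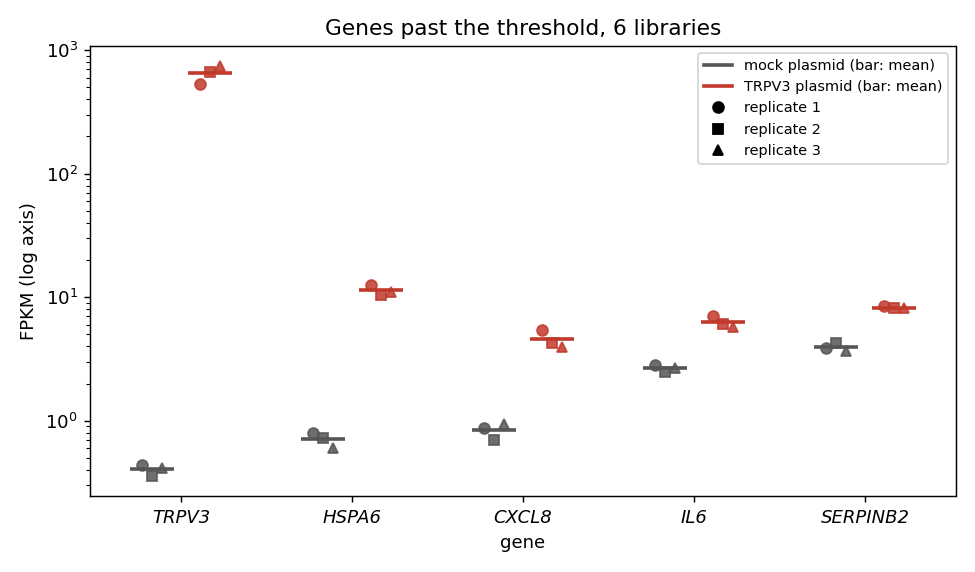
FPKM (log axis) of the 5 genes that passed the threshold, with grey marks for the 3 mock libraries, red marks for the 3 TRPV3 libraries, marker shapes for replicates and bars for group means. TRPV3 sits near 0.404 FPKM with the mock plasmid and 648 FPKM with the TRPV3 plasmid, and in all 5 genes every red mark lies above every grey mark.

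At an unadjusted limma p under 0.05 there were 546 genes, 399 higher and 147 lower with TRPV3. The 546 were fewer than the 5% of the 12177 genes tested that chance alone gives on average. That count depended on the libraries used. It ran from 301 without mock replicate 3 to 886 without TRPV3 replicate 3, and was 860 without TRPV3 replicate 1. The groups did not overlap in 1155 genes with every TRPV3 library above (9.49% of those tested) and in 656 with every TRPV3 library below (5.39%), where chance gives 5% each way. The calls of CXCL8, IL6 and SERPINB2 were lost without the filter on low values (limma adjusted p = 0.0963, 0.177 and 0.0963). Called genes numbered 2, 3 and 3 without mock replicate 1, 2 or 3. They numbered 8, 2 and 3 without TRPV3 replicate 1, 2 or 3. TRPV3 and HSPA6 were called each time. CXCL8 stayed called only without TRPV3 replicate 1 or 3, and IL6 and SERPINB2 only without TRPV3 replicate 1. The third gene was MIR378G, lower with TRPV3, without mock replicate 2. It was MIR4740 without mock replicate 3, both named after their values were seen. An alternative chosen after the data were seen, limma-voom on the recovered reads, called 6 genes (6 higher, 0 lower) with all libraries and 67 (66 higher, 1 lower) without TRPV3 replicate 1.

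The chemokine list was shifted upward with TRPV3. Of 7 measured chemokines 1 rose over all genes tested (CXCL8) and 4 rose adjusted over the list alone, and the list median was 0.87 (camera adjusted p = 1.02e-08; adjusted p = 0.0288 with an estimated correlation). CXCL1, also a neutrophil attractant, was at 5.58 ± 1.15 FPKM with mock and 13.9 ± 3.40 FPKM with TRPV3 (log2 fold change 1.17, SE 0.19, limma adjusted p = 0.279 over all genes). The other 2 that passed over the list alone, named after their values were seen, were CXCL2 (0.87, SE 0.10) and CXCL3 (0.92, SE 0.14). CXCL6 (0.19) and CCL28 (0.09), also named after their values were seen, did not pass. The abundant CXCL16 was at 38.8 ± 1.08 and 40.0 ± 1.36 FPKM, a difference of 0.04 that turned negative under 4 of the alternatives. The chemokine median was 0.79 without TRPV3 replicate 1, and 0.05 over 21 members without the filter on low values, where 15 were above 0.

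Of 11 measured inflammatory cytokines 1 rose over all genes (IL6) and 6 rose adjusted over the list alone, with a list median of 0.34 (camera adjusted p = 1.31e-07; adjusted p = 0.0288 with an estimated correlation). The 5 beside IL6, named after their values were seen, were IL11 (log2 fold change 0.77), IL1A (0.51), IL32 (0.39), LIF (0.34) and IL23A (0.29). Of the most abundant members, IL18 was at 19.3 ± 0.429 and 25.9 ± 6.80 FPKM, and IL1RN, the interleukin 1 receptor antagonist, at 20.4 ± 0.467 and 22.1 ± 2.17 FPKM; neither passed the test. Their log2 fold changes of 0.38 and 0.11 were 0.18 and 0.03 without TRPV3 replicate 1. IL1B and TNF lay under the filter of 1 FPKM. IL1B had 30, 18 and 32 reads in the mock libraries and 46, 24 and 40 in the TRPV3 libraries, and TNF had 0, 0 and 1 against 0, 3 and 0 reads, so that a change of TNF was not detectable at this depth. The cytokine median was 0.24 without TRPV3 replicate 1, and 0.08 over 28 members without the filter on low values. Over the list alone 2, 3 and 2 cytokines passed without mock replicate 1, 2 or 3, then 7, 2 and 4 without TRPV3 replicate 1, 2 or 3, and 2 with the length trend removed.

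The NF-kB list, which holds subunits, inhibitors and targets of that pathway, was shifted upward with a smaller median. Of its 21 measured members 0 passed over all genes tested by limma, where 3 passed by voom without TRPV3 replicate 1, and 6 rose adjusted over the list alone. The median was 0.20 (camera adjusted p = 1.31e-07; adjusted p = 0.0288 with an estimated correlation). TNIP1, an inhibitor of NF-kB signalling, was at 55.4 ± 1.14 FPKM with mock and 75.1 ± 6.20 FPKM with TRPV3 (0.43, SE 0.09). Named after their values were seen, TNFAIP3, the A20 inhibitor of the pathway, had 0.58, RELB 0.48, IER3 0.44, IRAK2 0.44 and NFKB2 0.35, all passing over the list alone. NFKBIA, the inhibitor I-kappa-B alpha, was at 29.2 ± 0.730 and 36.3 ± 5.98 FPKM and did not pass (0.29, or 0.16 without TRPV3 replicate 1). PTGS2, which encodes the inducible cyclooxygenase, was at 0.909 ± 0.02 and 1.15 ± 0.200 FPKM and did not pass. The NF-kB median was 0.16 without TRPV3 replicate 1. The members passing over the list alone were 2, 0 and 5 without mock replicate 1, 2 or 3 and 9, 6 and 6 without TRPV3 replicate 1, 2 or 3.

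Interferon-stimulated genes, the antiviral genes that type I interferons induce, were higher across most of the list. Of 27 measured members 24 had a fold change above 0, 9 rose adjusted over the list alone and 0 passed over all genes by limma, where 11 passed by voom without TRPV3 replicate 1. The list median was 0.27 (camera adjusted p = 1.22e-13; adjusted p = 0.0288 with an estimated correlation). ISG15, a ubiquitin-like modifier, was at 45.9 ± 3.65 FPKM with mock and 83.0 ± 24.3 FPKM with TRPV3, and IFI6 at 27.5 ± 1.08 and 41.2 ± 7.17 FPKM. Named after their values were seen, IFI44 had a log2 fold change of 0.84, OASL 0.65, IFIT2 0.64, OAS1 0.59 and MX1 0.40. Without TRPV3 replicate 1 the median was 0.27, and the list's adjusted p was 0.0955 with an estimated correlation (camera, limma).

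Immediate-early and calcium-responsive genes, which encode transcription factors and phosphatases switched on soon after a signal, were shifted upward as a list. Of 19 measured members 19 had a fold change above 0 (18 with the length trend removed), some of them far inside their error, such as KLF6 (0.02, SE 0.11), named after its values were seen. Adjusted over the list alone 9 rose, and 0 passed over all genes by limma, where 5 passed by voom without TRPV3 replicate 1. For this list the median was 0.24 (camera adjusted p = 7.1e-14; adjusted p = 0.0288 with an estimated correlation). FOSL1, a subunit of the AP-1 transcription factor, was at 45.1 ± 2.46 FPKM with mock and 78.3 ± 4.4 FPKM with TRPV3 (log2 fold change 0.78, SE 0.08, limma adjusted p = 0.0605), and passed without TRPV3 replicate 1 (limma adjusted p = 0.0114). MYC was at 36.4 ± 0.976 and 42.4 ± 1.25 FPKM (0.21, SE 0.07) and passed over the list alone. Named after their values were seen, ATF3 had 0.66, JUN 0.61, RCAN1, a calcineurin regulator, 0.51 and DUSP5, a phosphatase of ERK kinases, 0.40, all passing over the list alone. Without TRPV3 replicate 1 the median was 0.20. The count over the list alone was 5 without mock replicate 2 and 6 to 11 when 1 of the other libraries was left out.

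With an estimated correlation, 5 of the 19 lists were called with all 6 libraries, 4 without TRPV3 replicate 1, and 0 when any of the other 5 libraries was left out, or without TRPV3 replicate 1 and mock replicate 3 together. With a filter of 5 FPKM 0 of 16 lists were called, and chemokines and cytokines had too few members to test. Under TPM scaling 2 of the 5 above were called, the chemokines and the cytokines. With the preset correlation, these 5 lists were called in every case of a left-out library.

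**Figure D2:**
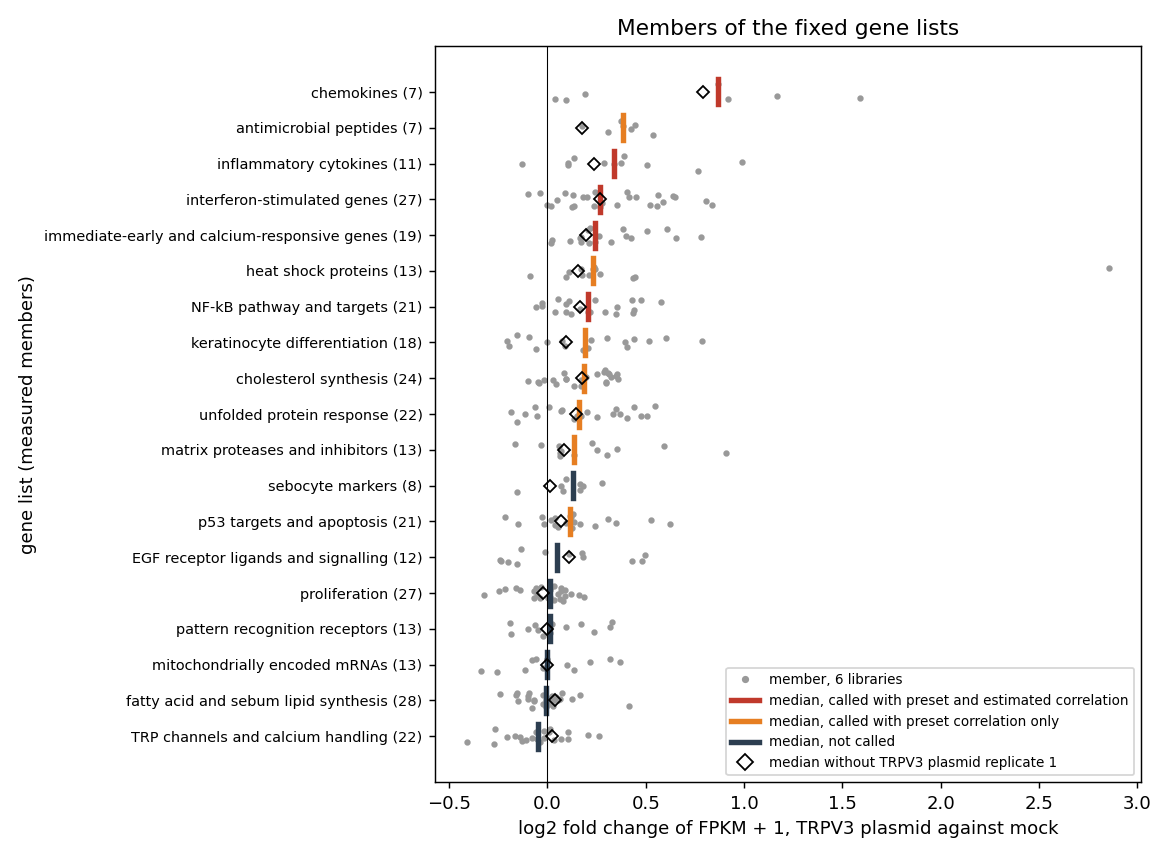
Log2 fold change of FPKM + 1 (TRPV3 plasmid against mock) of the measured members of each gene list, with grey points for genes, a bar for the list median and an open diamond for the median without TRPV3 replicate 1. The chemokine median (0.87) lies farthest to the right and HSPA6 (2.86) is the highest point, whereas the lists of proliferation, mitochondrial mRNAs and fatty acid synthesis have medians within 0.02 of 0.

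Heat shock and protein-folding genes were higher as lists with the preset correlation. With an estimated one they were not called with the deposited values, and both were called with the length trend removed (camera adjusted p = 0.0258 each) and with no filter (camera adjusted p = 0.0404 each). Of 13 measured heat shock proteins 1 rose over all genes (HSPA6) and 3 rose adjusted over the list alone, with a median of 0.23 (camera adjusted p = 1.02e-08; adjusted p = 0.114 with an estimated correlation). The other 2, HSPA1A and HSPA1B, named after their values were seen, are near-identical genes, each with a log2 fold change of 0.44. The constitutive HSPA8 was at 294 ± 11.8 and 347 ± 31.7 FPKM (0.23, SE 0.10), and HSP90AA1 at 412 ± 14.5 and 439 ± 16.6 FPKM, a difference of 0.09 that was -0.14 under quantile normalization; neither passed. Of 22 measured genes of the unfolded protein response 0 passed over all genes by limma (4 by voom without TRPV3 replicate 1) and 3 rose adjusted over the list alone, with a median of 0.16 (camera adjusted p = 4.64e-05; adjusted p = 0.125 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, was at 227 ± 5.73 and 303 ± 27.2 FPKM (0.41, SE 0.10) and passed over the list alone. CALR was at 273 ± 11.2 and 307 ± 27.9 FPKM, a difference of 0.17 that turned to -0.03 under quantile normalization, and did not pass. Without TRPV3 replicate 1 the medians were 0.16 for heat shock proteins and 0.14 for the unfolded protein response, and 6 and 7 members passed over the list alone, 2 of the heat shock proteins over all genes. The unfolded protein response count over the list alone was 0 without mock replicate 1, 2 or 3 or TRPV3 replicate 2, 5 without TRPV3 replicate 3 and 6 with the length trend removed.

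The fatty acid list was not called and the cholesterol list was called at the preset correlation; the difference between them was not tested. Of 28 measured genes of fatty acid and sebum lipid synthesis 0 passed over all genes by limma or voom, 0 passed over the list alone, and the median was -0.01 (camera adjusted p = 0.693). Named after their values were seen, FASN, the fatty acid synthase, was at 66.0 ± 4.84 and 59.8 ± 10.5 FPKM, SCD at 227 ± 22.4 and 219 ± 42.6 FPKM, and PPARG at 7.28 ± 0.287 and 8.33 ± 1.02 FPKM. Their log2 fold changes of -0.15, -0.07 and 0.17 were -0.00208, 0.11 and 0.09 without TRPV3 replicate 1. Of 24 measured genes of cholesterol synthesis 20 had a fold change above 0, but 0 passed over the list alone by limma; without TRPV3 replicate 1, 10 passed over the list alone by limma and 3 over all genes by voom. The list median was 0.19 (camera adjusted p = 1.6e-06; adjusted p = 0.114 with an estimated correlation, and 0.0327 with the length trend removed as well). HMGCS1, which makes the precursor of mevalonate, was at 85.4 ± 7.35 and 106 ± 10.5 FPKM (0.31, SE 0.11), and did not pass by limma with all libraries. Of 8 measured sebocyte markers 0 passed (limma; 0 by voom without TRPV3 replicate 1), with a median of 0.13 (camera adjusted p = 0.158) that was 0.02 without TRPV3 replicate 1. FASN and PPARG stand in both the sebocyte and the fatty acid list.

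Of 18 measured keratinocyte differentiation genes 2 rose adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.00938; adjusted p = 0.291 with an estimated correlation); the 2, named after their values were seen, were SPRR2D (0.79) and SPRR1B (0.60), both cornified envelope proteins. That count was 0 without mock replicate 1, 2 or 3, and 3, 1 and 1 without TRPV3 replicate 1, 2 or 3. The list's call at the preset correlation was lost with the length trend removed (median 0.08, camera adjusted p = 0.107). It was also lost at 5 FPKM or more, and without TRPV3 replicate 1 and mock replicate 3 together (camera adjusted p = 0.196). The abundant keratins KRT6A and KRT5 were at 425 ± 16.1 against 448 ± 10.7 FPKM and 160 ± 15.1 against 149 ± 5.24 FPKM and did not pass by limma, and the difference of KRT6A was -0.17 under quantile normalization. By voom, KRT5 was called lower without TRPV3 replicate 1 and mock replicate 3 together (-0.19, limma-voom adjusted p = 0.0102), and KRT17, named after its values were seen, was called higher without TRPV3 replicate 1 (0.26, limma-voom adjusted p = 0.0208). Of 7 measured antimicrobial peptide genes 0 passed over the list alone; the median was 0.38 (camera adjusted p = 0.000289; adjusted p = 0.238 with an estimated correlation) and 0.18 without TRPV3 replicate 1. In SLPI, a secreted protease inhibitor, that library held 836 FPKM and the other 2 TRPV3 libraries 474 and 477 FPKM, against 440 ± 21.8 FPKM with mock. LCN2, the iron-binding lipocalin, was at 208 ± 10.6 and 261 ± 60.2 FPKM (0.31, or 0.13 without TRPV3 replicate 1).

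Of 13 measured matrix proteases and their inhibitors 1 rose over all genes (SERPINB2) and 3 rose adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.000259; adjusted p = 0.137 with an estimated correlation). All 3 belong to the plasminogen system: beside SERPINB2 they were PLAUR (0.59) and PLAU (0.35), named after their values were seen. The count over the list alone was 1 without mock replicate 1, 2 or 3, and 3, 2 and 3 without TRPV3 replicate 1, 2 or 3. TIMP1 was at 68.7 ± 1.78 and 84.6 ± 26.7 FPKM and TIMP2 at 75.2 ± 1.73 and 73.6 ± 2.09 FPKM, and neither passed. The fold change of TIMP1 was 0.25, and 0.01 without TRPV3 replicate 1. Of 21 measured p53 targets and apoptosis genes 1 rose adjusted over the list alone, PMAIP1 (0.62), named after its values were seen; the median was 0.12 (camera adjusted p = 0.00374; adjusted p = 0.148 with an estimated correlation). The anti-apoptotic MCL1 was at 71.0 ± 0.634 and 73.9 ± 7.82 FPKM and BCL2L1 at 65.0 ± 1.16 and 70.0 ± 9.66 FPKM, differences of 0.05 and 0.10 that were -0.07 and -0.02 under quantile normalization. Without TRPV3 replicate 1 the medians were 0.09 for matrix proteases, 0.07 for p53 targets and 0.09 for keratinocyte differentiation.

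Among the EGF receptor ligands and signalling genes 3 of 12 rose adjusted over the list alone. Named after their values were seen, these were AREG (0.50), HBEGF (0.48) and EREG (0.43), all ligands. The other measured ligands, TGFA (0.18) and BTC (0.11), also named after their values were seen, did not pass. The list's count of rising members was 0, 0 and 1 without mock replicate 1, 2 or 3, and 4, 0 and 0 without TRPV3 replicate 1, 2 or 3; without TRPV3 replicate 1, 1 member fell over the list alone. ERBB2, a receptor of this family named after its values were seen, was at 20.2 ± 0.513 and 17.4 ± 0.539 FPKM, did not pass by limma, and was called lower by voom without TRPV3 replicate 1 and mock replicate 3 (-0.21, limma-voom adjusted p = 0.0206). The list itself was not called, with a median of 0.05 (camera adjusted p = 0.394), and was called without TRPV3 replicate 1, where the median was 0.11 (camera adjusted p = 0.00151; adjusted p = 0.267 with an estimated correlation). Other TRP channels and calcium handling genes had a median of -0.05 over 22 members (camera adjusted p = 0.226), with 0 passing over the list alone, and 0.02 without TRPV3 replicate 1. Pattern recognition receptors had 0.01 over 13 members (camera adjusted p = 0.674) and 0 passing. Proliferation genes had 0 of 27 passing and a median of 0.01, although the mean and the test pointed down (camera adjusted p = 0.701); the list was called lower under quantile normalization (median -0.10, camera adjusted p = 0.000491; adjusted p = 0.138 with an estimated correlation) and without TRPV3 replicate 1 and mock replicate 3 together (median -0.05, camera adjusted p = 0.0218; adjusted p = 0.192 with an estimated correlation). Mitochondrially encoded mRNAs had 0 of 13 passing, a median of -0.0005 and a mean of 0.02 (camera adjusted p = 0.848), pointed down under the TPM and quantile scalings, and were called lower without TRPV3 replicate 1 and mock replicate 3 together (median -0.13, camera adjusted p = 0.000234; adjusted p = 0.335 with an estimated correlation). For the 4 lists with 0 passing in this paragraph, voom with all libraries or without TRPV3 replicate 1 also called 0 members over all genes. Voom without both libraries called MT-ATP6 (-0.17), MT-ND5 (-0.16) and MT-CYB (-0.17) lower and CGAS (0.33) higher, all named after their values were seen.

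Markers of other cell types were mostly under the filter of 1 FPKM. Of 12 fibroblast markers 1 was measured (COL1A1, 2.49 ± 0.249 and 2.09 ± 0.0652 FPKM), of 10 macrophage markers 1 (CD74, 12.6 ± 0.580 and 13.9 ± 1.26 FPKM), of 9 melanocyte markers 1 (MITF, 3.89 ± 0.399 and 3.54 ± 0.473 FPKM) and of 8 endothelial markers 2 (EGFL7, 15.2 ± 0.974 and 17.5 ± 4.87 FPKM, and CDH5, 1.19 ± 0.174 and 1.38 ± 0.0837 FPKM). These 4 lists were too short for a list test, and none of the 5 genes passed the limma test.

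A pair of libraries stood apart from the rest of their groups. TRPV3 replicate 1 lay at 36.3 on a first principal component that took 57.9% of the variance, with the other 5 libraries between -13.0 and -2.73. Its difference from the other libraries followed gene length: of 5 length bins of protein-coding genes, the shortest had a median difference of 0.37 and the longest -0.31, and 73 ribosomal protein genes had a median of 0.64. Mock replicate 3 had at least 1 read in 34467 genes, where the other 5 libraries had between 22311 and 23072. Without both libraries limma called 10 genes (9 higher, 1 lower), 5 of them the 5 named above, and voom called 144 (107 higher, 37 lower); both were chosen after the data were seen.

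**Figure D3:**
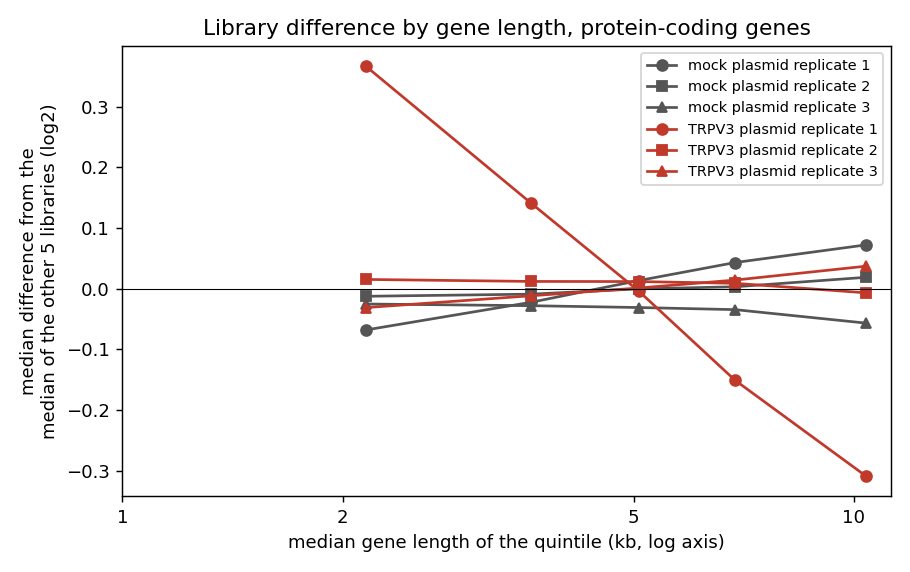
Median log2 difference of each library from the median of the other 5, for protein-coding genes in 5 bins of gene length (kb, log axis), with grey for mock and red for TRPV3 libraries. TRPV3 replicate 1 runs from 0.37 in the shortest bin to -0.31 in the longest, while the medians of the other 5 libraries lie between -0.07 and 0.07.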

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

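Tests with the length trend removed, total reads, voom, protein-coding genes or both doubted libraries left out were chosen after seeing the data. TRPV3 and HSPA6 were called in every setting with a test, and TRPV3 had log2 fold changes of 8.74 to 10.8. Limma called 5 genes, against 2 with no filter, 3 at 5 FPKM or more, 3 with the replicate number as a block, 3 with a 2-fold minimum, 2 to 8 with 1 library left out, 10 without TRPV3 replicate 1 and mock replicate 3, 148 by voom with sample quality weights (119 higher, 29 lower), 67 by voom without TRPV3 replicate 1 and 144 by voom without both libraries. The quality weights gave TRPV3 replicate 1 a weight of 0.0745. The block left CXCL8, IL6 and SERPINB2 at limma adjusted p = 0.129, 0.263 and 0.309. The model without pairs was fixed beforehand, since the labels do not say that the numbers pair. Residuals of same-numbered libraries correlated at -0.272, -0.0387 and -0.168. This check cannot decide on pairing with 3 libraries per group: mock replicate 3 also correlated at -0.157 with TRPV3 replicate 2. Median-of-ratios scaling repeats the factor already in the deposited values and tests nothing. Of 19 lists 12 were called at the preset correlation, 8 of 16 tested at 5 FPKM or more, 13 of 23 with no filter and 11 to 14 of 19 in the other settings. With an estimated one 5 were called, and 0 to 10 across the other settings: 0 of 16 tested at 5 FPKM or more, 0 with the block, without both libraries and when 1 library other than TRPV3 replicate 1 was left out, 3 under TPM scaling, 2 of them among the 5, but 7 with total reads, 8 with quality weights, 8 with the length trend removed and 10 of 23 tested with no filter, each including the 5, heat shock and cholesterol. With all libraries and the deposited values 7 lists called at the preset correlation were not called at the estimated one, with medians above 0: unfolded protein response 0.16, heat shock 0.23, cholesterol 0.19, p53 0.12, keratinocyte 0.19, antimicrobial 0.38 and matrix proteases 0.14. With no filter, which adds members of low level, medians fell to 0.05 for chemokines, 0.08 for cytokines, 0.08 for keratinocyte, 0.11 for antimicrobial and 0.06 for matrix protease genes, and were -0.0054 for pattern recognition (called higher by the test, camera adjusted p = 0.0453; adjusted p = 0.253 with an estimated correlation), -0.0079 for fatty acid and 0.0134 for proliferation genes, the last 2 with the test turned. At 5 FPKM or more, keratinocyte genes had -0.0017 (call lost), and EGF receptor (-0.14) and mitochondrial (-0.00045) lists turned. Under TPM scaling mitochondrial mRNAs (-0.0949), CXCL16 (-0.0518), HSP90AA1 (-0.00080), MCL1 (-0.0418) and KRT6A (-0.0196) turned; under quantile normalization mitochondrial mRNAs (-0.0470), CXCL16 (-0.0406), CALR (-0.0290), HSP90AA1 (-0.14), MCL1 (-0.0658), BCL2L1 (-0.0211) and KRT6A (-0.17) turned, and proliferation was called lower (-0.10). With 1 library left out, ranges were -0.0378 to 0.0380 for fatty acid, 0.0940 to 0.23 for keratinocyte, -0.13 to 0.0487 for mitochondrial, -0.0776 to 0.0229 for TRP channel and 0.0165 to 0.11 for EGF receptor lists, and -0.0127 to 0.17 for BCL2L1. With the length trend removed keratinocyte genes had 0.0786 (call lost), and mitochondrial mRNAs (-0.14), CXCL16 (-0.0462) and KRT6A (-0.0072) turned, as CXCL16 did with total reads (-0.0060). By voom with quality weights, fatty acid (0.0241), TRP channel (0.0043) and mitochondrial (-0.0363) lists and TIMP1 (-0.0122) turned, keratinocyte genes (0.0721) lost the call and the EGF receptor list (0.11) gained it. By voom without TRPV3 replicate 1, fatty acid (0.0408) and TRP channel (0.0236) lists and BCL2L1 (-0.0130) turned, keratinocyte genes (0.12) lost the call and the EGF receptor list (0.14) gained it. Without both libraries, by limma and by voom, the tests of fatty acid (0.0097 and 0.0097), TRP channel (-0.0123 and -0.0152) and mitochondrial lists (-0.13 and -0.13) and BCL2L1 (-0.0094 and -0.0098) turned, keratinocyte genes (0.0424 and 0.0574) lost the call, and proliferation (-0.0493 and -0.0497) and the EGF receptor list (0.0629 and 0.0831) gained one. With an estimated correlation these and the other calls gained by proliferation and the EGF receptor list were lost (camera adjusted p = 0.138 to 0.267). Where the alternative did not itself use fewer genes or libraries, the cause was not tested. Calls lost at an estimated correlation may also reflect the few degrees of freedom of that test. Over the named genes and alternatives, 548 results stayed on their side of the threshold, 26 gained a call, 21 lost one and 18 turned. Depth limits genes such as TNF, with at most 3 reads in a library.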

Other observations

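All genes in this paragraph and the next were chosen after their values were seen, as were the 2 voom comparisons in them and 6 of the tests below: both length tests and the TRPV3 dose for TRPV3 replicate 1, and the sequencing depth the share of the 10 highest genes and the density by gene class for mock replicate 3. Voom without TRPV3 replicate 1 called 66 genes higher and 1 lower; beside TRPV3, 44 of those higher stood in a fixed list and 21 in none. Among the 21, INHBA, a subunit of activin A, had a log2 fold change of 1.16 (SE 0.12, limma-voom adjusted p = 0.000237), and G0S2, an inhibitor of the lipase that releases fatty acids from droplets, had 0.83 (SE 0.09, limma-voom adjusted p = 0.000363). LAMB3 and LAMA3, subunits of the basement membrane protein laminin 332, had 0.43 (SE 0.05) and 0.30 (SE 0.06), and the chloride channel gene CFTR had 0.71 (SE 0.09). ALPP, a placental alkaline phosphatase, was the 1 gene called lower, at -0.47 (SE 0.09, limma-voom adjusted p = 0.0253). Of 5 measured EGF receptor ligands, EREG (0.62), HBEGF (0.70), AREG (0.35) and TGFA (0.31) were called higher there, and BTC was not called. With all 6 libraries voom called 6 genes, and none of the genes in this paragraph.

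Genes were also called from 4 libraries and read in the other 2. Voom on TRPV3 replicates 2 and 3 against mock replicates 1 and 2 called 106 genes higher beside TRPV3 and 37 lower. In the unused pair, TRPV3 replicate 1 against mock replicate 3, 95 of the 106 were higher, where 53.9% of all tested genes were, with a median difference of 0.41; 26 of the 37 were lower. With length trends removed the counts were 95 of 106, against 49.5% of all tested genes, and 28 of 37, with a median difference of 0.32. This pair holds 1 library per group, so it gives no spread.

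TRPV3 replicate 1 stood apart from the other 5 libraries. A gene length bias may account for part of it: the difference from the other 2 TRPV3 libraries correlated with gene length at rho = -0.528. Annotated length was not the whole of it, since with the trend removed its root mean square difference, 0.350, was still 1.58 times that of the next library. The trend used the merged length of all annotated exons, so a bias on the length of the expressed transcripts cannot be excluded as the whole. GC content stays open, with rho = 0.146 after the length trend was removed, between the bounds of 0.1 and 0.3 set for it. A larger dose of TRPV3 was not seen. The TRPV3 level of this library was 0.761 of the mean of the other 2 TRPV3 libraries, and 0.914 with the length trend removed. Both values lie below that mean. The second is within 2 SD of those 2, so the bounds set for the test decide neither way. The length of the plasmid transcript is not given in the sources used here. A shorter transcript than annotated would lower the second value rather than raise it, since short genes were higher in this library.

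Mock replicate 3 had reads in 9477 of 29953 genes that were silent in the other 5 libraries, 20768 reads in all or 0.119% of the library. Deeper sequencing is argued against, since its total was 0.947 of the highest of the others. Thin background reads, such as genomic DNA, may be the source: the reads correlated with gene length at rho = 0.418. RNA of another cell type is argued against as the whole source, since reads per kb in protein-coding genes (0.629) were 0.946 times those in processed pseudogenes (0.664), where mRNA would fall mainly in the former. As a part it stays open: a test on the highest gene (37 reads) met neither of its bounds, the share of the 10 highest genes that replaced it, 1.09%, was already bounded by that value, and no biological explanation was tested.

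The lists of chemokines, cytokines, the NF-kB pathway, interferon-stimulated and immediate-early genes were higher with TRPV3. The length bias of TRPV3 replicate 1 is argued against as the whole cause, since 5 of the 5 lists were called at the preset correlation both without that library and with length trends removed, though with an estimated correlation 4 of 5 were called without it. A load of overexpressed protein on folding may contribute and stays open: without that library the unfolded protein response list had a median of 0.145, and it and the heat shock list both had a camera adjusted p = 0.0955 with an estimated correlation, whereas with length trends removed and all libraries both had 0.0258. The only control was a mock plasmid, so TRPV3 cannot be told apart from any other overexpressed protein. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10, the real one, gave 5 genes, and the highest other gave 1. Leaving out TRPV3, the transfected gene, the real split gave 4. At the preset correlation 1 of the 10, the real one, gave 12 lists, and the highest other gave 5.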
